A study of Mus musculus with 9 samples.

How the data were processed

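Expression was measured in aortic valve explants from C57BL/6J mouse pups taken at postnatal day 1. Per the labels, each sample pooled the valves of 5 to 6 pups, which were cultured on floating filters for 48 hours with DMSO (0.001%), with 1 µmol/L all-trans retinoic acid (ATRA) or with LE540, a retinoic acid receptor antagonist. The labels give neither the dose nor the vehicle of LE540, nor the sex of the pups. Per the labels, total RNA was amplified and biotin-labelled with Nugen kits (Ovation Pico WTA, Exon Module, Encore Biotin), and each pool was hybridized to its own array. There were 3 arrays per group and 9 in all.

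The deposited values are RMA intensity values, 1 per probe set and array. The submitters' processing notes name Affymetrix Expression Console 1.1 and RMA, a method that corrects background, quantile-normalizes arrays and summarizes the probes of a probe set. The deposited intensity values ran from 4.09 to 17798.2 with array medians of 123.61 to 128.13, which is a linear scale, so log2 was taken before any test. The processing notes name no annotation and no genome build, so no positions are given. Precision is limited by the number of arrays, and no array has a depth in counts.

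The value table held 28270 rows. The annotation paired 23397 probe sets with at least 1 gene symbol, and these were tested: 21780 had 1 symbol and 1617 had several. The other 4873 rows, which have no listed gene and include control probe sets, were left out of the counts. Of the Entrez identifiers of the tested probe sets, 21689 were found in the RefSeq gene table, and 0 symbols had to be updated. For gene lists, each of 19934 genes was represented by the probe set with the highest mean over the 9 arrays, a choice that matters for 996 genes with several probe sets.

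Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 3 groups over all 9 arrays (6 residual degrees of freedom, 2.725 prior degrees of freedom) gave the contrasts ATRA vs DMSO, LE540 vs DMSO and ATRA vs LE540, each two-sided. A probe set passed at a Benjamini-Hochberg adjusted p under 0.1, and the subset that also changed over 2-fold is given beside each count. Both thresholds are those of the series' design text. "Rose" and "fell" are used for what passed. Intensities are means ± SD over the 3 arrays of a group, and log2 changes are given with the standard error (SE) of the fit.

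Before the data were examined, 36 gene lists were fixed, 9 of them markers of other cell types that the dissected tissue could hold. List members with no probe set here were not analysed. Each list was tested with camera in limma (preset correlation between genes of 0.01, adjusted over the 36 lists within a comparison), against all other genes. The same test with an estimated correlation, and fry, which tests the list by itself, were run beside it. Member counts are given over all genes and adjusted over the list alone. Named genes follow a rule fixed before the data were examined: up to 10 largest rises and falls among passing probe sets whose treated and control arrays do not overlap (5 in ATRA vs LE540), with unnamed and predicted genes passed over; up to 4 passing members of each list, or else the 2 largest changes; and 10 measured retinoid, cartilage and bone genes whatever their values. The bone genes Runx2 and Spp1 were fixed by name too, but no values are given for them here. Genes named outside this rule are marked as such.

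Replicates with the same number were checked for shared variation by correlating their deviations from their group means across probe sets. For ATRA and DMSO arrays r was 0.143, 0.342 and 0.22, and for ATRA and LE540 arrays 0.261, 0.282 and 0.269, with each array closest to the array of its own number in 3 of 3 cases. For LE540 and DMSO arrays r was 0.00946, 0.215 and 0.126, and 1 of 3 arrays was closest to its own number. Values from a fit with the replicate number as a block are therefore given in ATRA vs DMSO and ATRA vs LE540 where they change a call or move a count by over 1.5 times, and for the genes that passed in LE540 vs DMSO.

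Because both treatments share the DMSO arrays, the correlation of their fold changes was compared with 100 simulations of unchanged groups of equal spread. Simulations with the spread of each group, without and with the correlation of equal replicate numbers, were added after seeing the data. Alternatives covered the arrays in the fit, normalization, filters on dim probe sets, the prior, array weights, thresholds and leaving out each array in turn. A Y-linked score, a cardiomyocyte score and a fit with 1 probe set per gene were added after seeing the data. The fit was tested on simulated data with 200 changed probe sets among 23397: it recovered 26% to 32% of 1.5-fold changes, 80% to 86% of 2-fold changes and 98% to 100% of 4-fold changes, with 15 false calls among 171 in ATRA vs DMSO, 19 among 174 in LE540 vs DMSO and 15 among 171 in ATRA vs LE540. With no simulated change it called 0, 0 and 1 probe sets. For lists, a simulated shift of 0.5 log2 in the retinoic acid targets was recovered at an adjusted p of 1.28e-13, but 6 of the 35 lists without a shift were called in that simulated set too. Over 60 simulated sets with no shift, 4.86% of list tests had an unadjusted p under 0.05. Genes were simulated independently of each other, whereas the estimated correlation within a list reached 0.74 for cholesterol synthesis. The simulated rates therefore cannot show how often lists of correlated genes are called without a shift. Figures were drawn with matplotlib 3.10.9.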

Results

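The series profiled gene expression in pooled mouse aortic valve explants on 9 one-colour arrays, 3 each for DMSO, ATRA and LE540. Array medians lay between 123.61 and 128.13 intensity units, and log2 values of any pair of arrays correlated at r = 0.958 to 0.990 across probe sets, which are not independent replicates. The first principal component held 32.5% of the variance and set LE540 replicate 1 apart at 63.7, with the other arrays between -21.5 and 13.9. That array correlated least with the rest (r = 0.958 to 0.970). The second component held 19.4%, and the arrays numbered replicate 2 of every group lay at its low end (-33.1 to -17.9).

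Sex-linked transcripts varied between the pools. The Y-linked score, the mean centred log2 value of 3 Y-linked genes, was -1.14 ± 1.33 in DMSO, 0.88 ± 0.79 in ATRA and 0.26 ± 1.54 in LE540 arrays (SD, n = 3 each). Xist, the RNA that silences an X chromosome in females, averaged 2595 ± 305 in DMSO, 602 ± 696 in ATRA and 1025 ± 847 in LE540 arrays. Group means of both signals thus differ in each comparison with DMSO, although the Y-linked scores of single arrays overlap between groups.

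The first comparison, ATRA vs DMSO, asks how added retinoic acid changed valve expression. ATRA raised genes that retinoic acid is known to induce. Tgm2 (probe set 10489204), a protein-crosslinking transglutaminase, rose 5.00-fold, from 112 ± 5.57 to 562 ± 53.2 (SD, n = 3 arrays each, log2 change 2.32, SE 0.11, adjusted p = 0.000228). Dhrs3 (10510129), which reduces retinaldehyde back to retinol, rose 7.01-fold, from 516 ± 203 to 3520 ± 1099 (log2 change 2.81, SE 0.34, adjusted p = 0.0508). Cyp26a1 (10462853), the hydroxylase that degrades retinoic acid, rose 2.37-fold, from 48.8 ± 5.44 to 116 ± 17.6 (log2 change 1.25, SE 0.16, adjusted p = 0.0512).

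The largest rise among probe sets with a listed gene was that of Piezo2 (10459353), a mechanically gated cation channel, which went from 164 ± 56.7 to 1360 ± 233 (8.51-fold, log2 change 3.09, SE 0.31, adjusted p = 0.0237). Its other 2 measured probe sets rose by 2.90 and 1.75 log2. Fap (10483081), a surface protease of activated fibroblasts, rose 6.70-fold, from 76.7 ± 11.0 to 514 ± 71.8 (adjusted p = 0.00372). Pparg (10540897), the nuclear receptor that directs fat cell differentiation, rose 5.98-fold, from 103 ± 19.5 to 615 ± 87.5 (adjusted p = 0.00213). Csn3, the casein of the kappa type, rose from 17.1 ± 1.94 to 93.5 ± 32.8, Enpp3, an enzyme that splits extracellular nucleotides, 5.27-fold to 416 ± 182, and Krt18, a keratin of simple epithelia, 3.54-fold to 297 ± 63.4. Heg1, a membrane protein needed for heart and vessel development, rose 3.27-fold to 2589 ± 265, and Lgr6, a receptor for R-spondins, by 0.70 log2 (adjusted p = 0.0984). Ccdc152 fell by 1.57 log2, from 43.0 ± 9.94 to 14.5 ± 3.48 (adjusted p = 0.082). The DMSO means of Csn3, Cyp26a1 and Ccdc152 lie below the lower quartile of every array (57.7 to 63.0), where signal over background is unknown, so the size of these changes is uncertain. Of the 16 genes that passed, the 4 outside the naming rule were Kbtbd11, Ak1, Zfp57 and Creb3l1, named after their values were seen; each rose, by 0.88 to 1.21 log2, although the other probe set of Kbtbd11 did not pass (0.43 log2, adjusted p = 0.999).

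**Figure D1:**
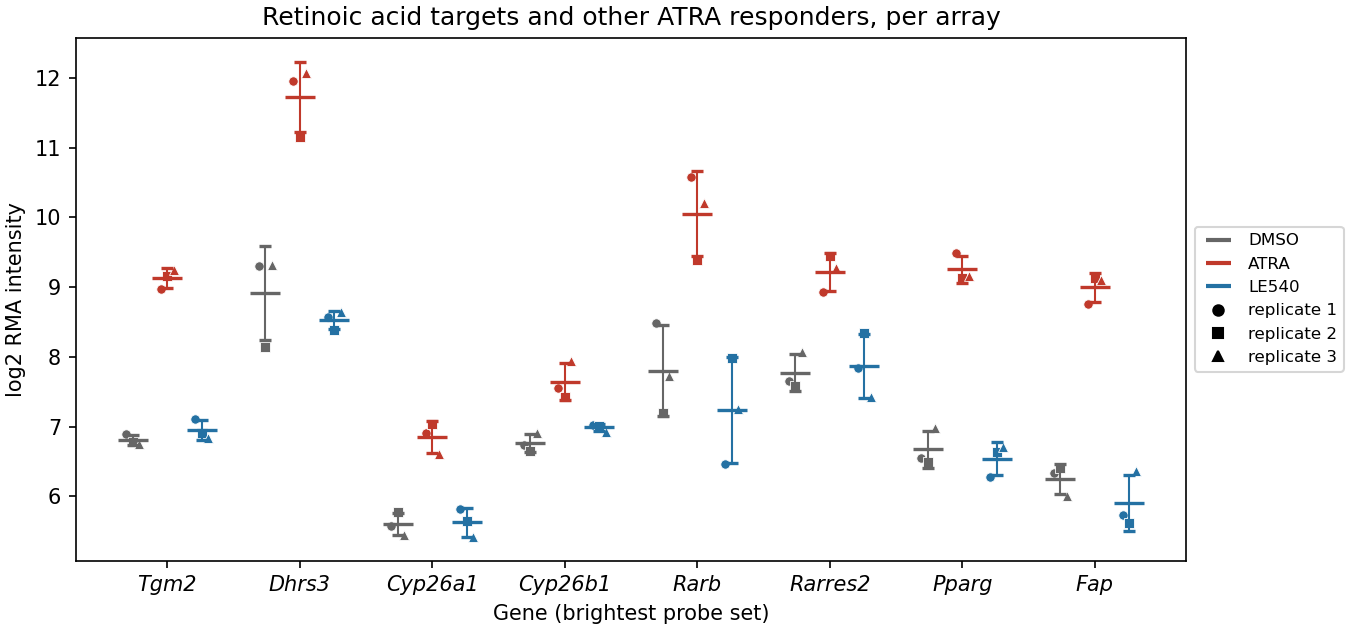
Log2 RMA intensity (vertical axis) of 8 genes (horizontal axis) in each array, by group (colour) and replicate number (marker shape); long dashes are group means and bars 1 SD (n = 3). The ATRA means of Tgm2, Pparg and Fap lie 2.32 to 2.74 log2 above the DMSO means, while Rarb, Rarres2 and Cyp26b1 did not pass in ATRA vs DMSO.

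In all, 19 of 23397 probe sets passed in limma, 18 up and 1 down, and 14 of them changed over 2-fold (13 up, 1 down); 1099 had an unadjusted p under 0.05. With the replicate number as a block, 29 passed, all 29 up, with 16 shared; the adjusted p of Ccdc152 was then 0.175 and that of Lgr6 0.164. The count was 4 without DMSO replicate 1 or without DMSO replicate 3, 10 without DMSO replicate 2, 6 without ATRA replicate 1, 6 without LE540 replicate 2 and 10 without LE540 replicate 3. It was 7 with the Y-linked score and 8 with the cardiomyocyte score as a covariate. Tgm2, Pparg, Fap and Csn3 passed with any 1 array left out, whereas the other 8 genes named by the rule did not, with adjusted p up to 0.521 (Lgr6, without DMSO replicate 1). With the Y-linked score Tgm2, Pparg, Fap and Piezo2 passed, while Csn3 (adjusted p = 0.118) and the other 7 genes named by the rule did not (up to 0.397).

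Retinoic acid targets rose as a list. All 17 measured members were higher with ATRA (median log2 change 0.29), 3 rose over all genes and 7 when adjusted over the list alone, and 14 did not pass over all genes (camera adjusted p = 4.62e-14, adjusted p = 0.0121 with an estimated correlation). Rarb, a retinoic acid receptor under retinoic acid control, went from 239 to 1125 without passing (log2 change 2.25, SE 0.46, adjusted p = 0.353). Cyp26b1, a paralogue of Cyp26a1, changed by 0.87 (SE 0.14, adjusted p = 0.146), and Stra6, a retinol uptake receptor, by 0.02 (SE 0.09, adjusted p = 0.999). Retinoid receptors and metabolism genes did not pass as a list (adjusted p = 0.479, median -0.03, mean 0.07), with Fabp5, a fatty acid and retinoic acid carrier, at 0.87 (SE 0.22).

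Cartilage and bone genes did not pass in ATRA vs DMSO. The cartilage list had 10 of 21 members higher (adjusted p = 0.976), with Sox9, the main cartilage transcription factor, at -0.13 (95% confidence interval -0.47 to 0.22), Acan at -0.07 (-0.91 to 0.77) and Col2a1 at 0.07 (-0.12 to 0.26), the matrix genes of cartilage. The bone formation list had 11 of 16 members higher (adjusted p = 0.168), with Alpl, the mineralizing phosphatase, at 0.43 (-0.18 to 1.04). Of the mineralization inhibitors 9 of 11 were higher (adjusted p = 0.392), and Mgp, a calcification inhibitor abundant in valves, was at -0.03 (-0.47 to 0.42). Ank, a pyrophosphate transporter and the 1 member to pass adjusted over the list alone, was lower, at -0.59 (SE 0.17, adjusted p = 0.766 over all genes). These intervals allow changes in either direction at 3 arrays per group.

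Extracellular matrix lists and the contractile list passed camera upward, although no single member passed over all genes. With an estimated correlation the matrix protease list alone held. Matrix proteases and inhibitors had 20 of 22 members higher (median 0.20, 0 passed over all genes and 2 rose adjusted over the list alone, camera adjusted p = 6.37e-05, adjusted p = 0.0974 with an estimated correlation), led by Mmp3, a stromelysin, at 2.36 (SE 0.64, adjusted p = 0.70). Smooth muscle and myofibroblast contractile genes had 13 of 16 higher (median 0.30, adjusted p = 6.37e-05, adjusted p = 0.387 with an estimated correlation), with Myl9, a myosin light chain, at 1.12 (SE 0.43). Elastic fibre genes had 10 of 14 higher (median 0.28, adjusted p = 0.0115, adjusted p = 0.387 with an estimated correlation), with Efemp1, a fibulin, at 1.82 (SE 0.46) and Fbln1, another fibulin, at 1.03 (SE 0.29). Fibrillar and beaded collagens had 14 of 17 higher (median 0.09, adjusted p = 0.0115, adjusted p = 0.473 with an estimated correlation), with the crosslinking oxidase Lox at 0.95 (SE 0.37). Proteoglycans and hyaluronan genes had 15 of 22 higher (median 0.12, adjusted p = 0.020, adjusted p = 0.473 with an estimated correlation), with the hyaluronan synthase Has2 at 1.02 (SE 0.36). Adjusted over the list alone, 2 elastic fibre genes, 1 collagen list gene, 1 proteoglycan list gene and 0 contractile genes rose. The collagen call was lost without ATRA replicate 3 (adjusted p = 0.13), and the proteoglycan call without DMSO replicate 2 (0.108, median -0.00298) or ATRA replicate 3 (0.145).

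Markers of other cell types moved in the same arrays. Endothelial markers had 19 of 20 members higher (median 0.28, 0 passed over all genes or adjusted over the list alone, adjusted p = 0.000332, adjusted p = 0.581 with an estimated correlation, 0.421 without ATRA replicate 2, where the median was 0.04). Emcn, an endothelial sialomucin, was at 1.39 (SE 0.70, adjusted p = 0.999, or 0.0601 with the replicate block). Cardiomyocyte markers had 15 of 19 lower (median -0.23, adjusted p = 0.0945, adjusted p = 0.636 with an estimated correlation), and this call was lost with the replicate block (0.118) and without DMSO replicate 1 (0.787, median -0.00154), ATRA replicate 1 (0.379), ATRA replicate 3 (0.879, median -0.13) or LE540 replicate 1 (0.117). Myh6, the atrial and adult myosin heavy chain, was at -0.85 (SE 0.65). Of the cardiomyocyte markers 16 of 19 lay above the array median, the brightest being Tnnt2 at 7538, and of the endothelial markers 12 of 20, the brightest being Cdh5 at 473; neither list shared a gene with another list. Macrophage markers were higher in 9 of 18 (adjusted p = 0.665).

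Growth and signalling lists also passed camera. Cell cycle genes had 21 of 23 members lower (median -0.25, adjusted p = 0.016, adjusted p = 0.636 with an estimated correlation, 0.364 with a median of -0.13 without DMSO replicate 2 and 0.258 without ATRA replicate 1), with Rrm2, a nucleotide reductase subunit, at -0.53 (SE 0.25). With the Y-linked score as a covariate that list turned to a median of 0.19 (adjusted p = 0.000839), and the calls of 7 other lists were lost: collagens (0.29), proteoglycans (0.256), valve mesenchyme transcription factors (0.27), Wnt signalling (0.27), Hox genes (0.522), the p53 response (0.876, median -0.14) and cardiomyocyte markers (0.57). Valve mesenchyme transcription factors had 15 of 20 higher (median 0.08, adjusted p = 0.016, adjusted p = 0.387 with an estimated correlation), with Twist2 at 0.82 (SE 0.15, adjusted p = 0.222). Hypoxia and glycolysis genes had 14 of 16 higher (median 0.12, adjusted p = 0.016, adjusted p = 0.387 with an estimated correlation, 0.257 with a median of 0.06 without ATRA replicate 2). The p53 response had 8 of 11 higher (median 0.18, adjusted p = 0.016, adjusted p = 0.473 with an estimated correlation, 0.162 without ATRA replicate 3). Adjusted over the list alone, 1 valve mesenchyme transcription factor rose and 0 genes of the cell cycle, hypoxia and p53 lists passed.

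Wnt signalling genes had 19 of 31 higher (median 0.05, 1 rose over all genes and 1 adjusted over the list alone, Lgr6, adjusted p = 0.0376, adjusted p = 0.473 with an estimated correlation, 0.136 with a median of 0.03 without DMSO replicate 1, 0.108 without DMSO replicate 2 and 0.111 with a median of 0.03 without ATRA replicate 3). Cholesterol synthesis genes had 12 of 15 higher (median 0.18, adjusted p = 0.0451, adjusted p = 0.636 with an estimated correlation, 0.602 with a median of 0.02 without DMSO replicate 1, 0.168 without ATRA replicate 2 and 0.604 with a median of -0.12 without ATRA replicate 3). TGF-beta and BMP signalling genes passed upward by camera (adjusted p = 0.0611, adjusted p = 0.629 with an estimated correlation) although their median was -0.04 and their mean 0.17, with 11 of 24 higher and 4 rising when adjusted over the list alone. Inhba, a subunit of activins, was at 1.75 (SE 0.57) and Bmp2, a bone morphogenetic protein, at 1.42 (SE 0.24, adjusted p = 0.189). That call was lost without DMSO replicate 3 (0.129, median -0.02), ATRA replicate 2 (0.133, median 0.03), ATRA replicate 3 (0.111, median 0.02) or LE540 replicate 3 (0.11). Hox genes had 15 of 22 higher (median 0.07, adjusted p = 0.0829, adjusted p = 0.632 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Their call was lost with the replicate block (0.101) and without DMSO replicate 1 (0.171), ATRA replicate 2 (0.216) or ATRA replicate 3 (0.111).

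In ATRA vs DMSO 20 lists did not pass, with adjusted p from 0.123 to 0.976. Among these were Notch signalling (0.173), Hedgehog signalling (0.665), tendon (0.805), cytokines and inflammation (0.168), interferon response (0.123), immediate early genes (0.202), oxidative phosphorylation (0.591), the unfolded protein and amino acid stress response (0.889) and the aryl hydrocarbon and oxidative stress response (0.638). Il33, an alarmin of the cytokine list, was at 2.09 (SE 0.40, adjusted p = 0.273). Lymphocyte (0.591), melanocyte (0.123), Schwann cell and neural crest (0.168), adipocyte (0.168), erythroid (0.388) and mesothelial and epithelial markers (0.154) did not pass either. Pparg of the adipocyte list and Krt18 of the epithelial list passed without their lists. Median, mean and test differed in sign for 7 of the 36 lists, of which 1 passed, TGF-beta and BMP signalling.

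The second comparison, LE540 vs DMSO, asks what a blocker of retinoic acid receptors changed. The 7 genes that passed all rose. Mt2 (probe set 10574023), a metallothionein that binds zinc and copper, rose 12.3-fold, from 587 ± 182 to 7290 ± 2731 (SD, n = 3 arrays each, log2 change 3.62, SE 0.39, adjusted p = 0.0917). Mt1 (10574027), the neighbouring metallothionein, rose 5.26-fold, from 871 ± 311 to 4427 ± 910 (log2 change 2.40, SE 0.30, adjusted p = 0.0917). In ATRA arrays Mt2 averaged 666 ± 342 and Mt1 1014 ± 239.

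Ddit3 (10366881), a transcription factor of the integrated stress response, rose 3.43-fold, from 1002 ± 99.1 to 3519 ± 938 (adjusted p = 0.0917). Hmox1 (10572897), the heme-degrading oxygenase, rose 3.26-fold, from 1018 ± 164 to 3357 ± 819. Mthfd2 (10545672), a mitochondrial enzyme of one-carbon metabolism, rose 3.44-fold to 1609 ± 174, Slc6a9 (10507500), a glycine transporter, 2.96-fold to 622 ± 167 (adjusted p = 0.0955), and Nnmt (10593219), which methylates nicotinamide, 2.75-fold to 411 ± 17.6. Each of these 7 genes was higher in 3 of 3 LE540 arrays than in any DMSO array, as the naming rule requires. Of all tested probe sets, 12.6% had no overlap between LE540 and DMSO arrays, in either direction.

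**Figure D2:**
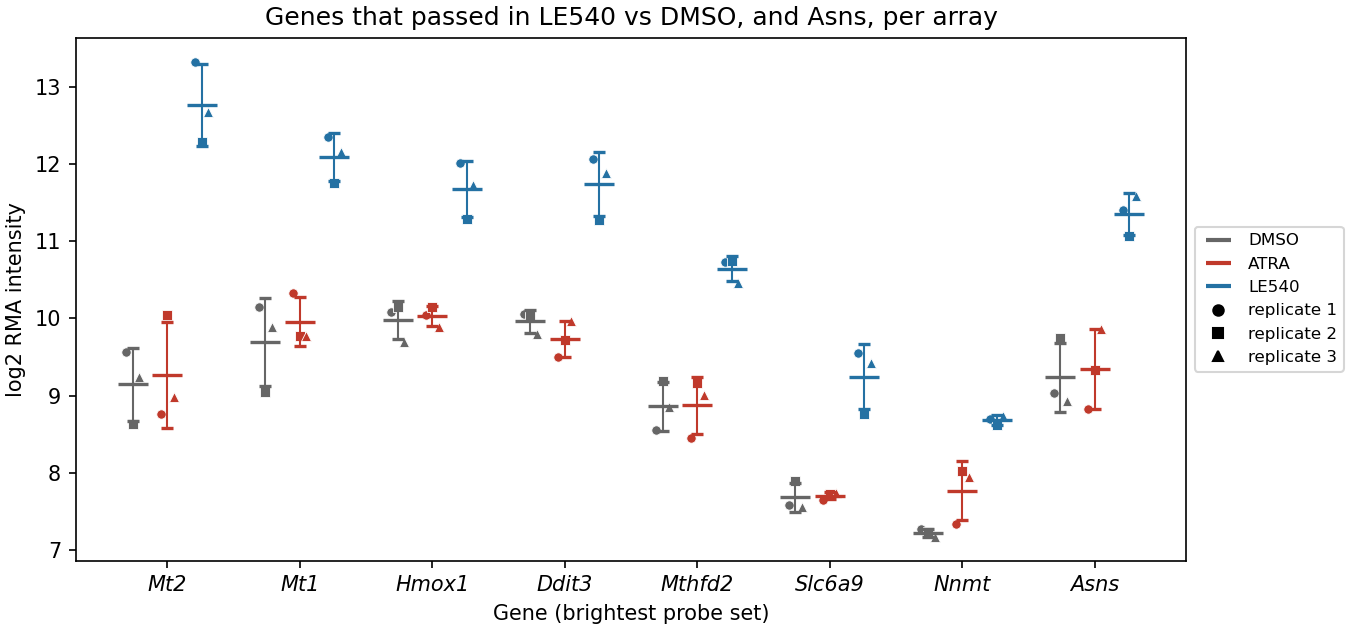
Log2 RMA intensity (vertical axis) of 8 genes (horizontal axis) in each array, by group (colour) and replicate number (marker shape); long dashes are group means and bars 1 SD (n = 3). Mean log2 values of Mt2 with LE540 lie 3.62 above DMSO; Asns passed in ATRA vs LE540 and not in LE540 vs DMSO.

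In limma 7 of 23397 probe sets passed, 7 up and 0 down, each over 2-fold, with 0.0917 as the lowest adjusted p; 2060 had an unadjusted p under 0.05, 1046 up and 1014 down. The 7 lie close to the threshold: 0 probe sets passed without DMSO replicate 1, 2 or 3 or without ATRA replicate 3, 1 without ATRA replicate 2, 1 without LE540 replicate 1 (none of the 7), 12 without ATRA replicate 1, 98 without LE540 replicate 2 and 297 without LE540 replicate 3. After quantile normalization, with all 28270 rows tested, or with the cardiomyocyte score as a covariate the count was 0. With the replicate number as a block 1 probe set passed, that of Mt1 (adjusted p = 0.0383), and the other 6 genes had an adjusted p of 0.114 to 0.164. With the Y-linked score as a covariate 6 of the 7 genes did not pass (0.115 to 0.2), Mthfd2 being the exception.

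The stress response list rose with LE540. Of the unfolded protein and amino acid stress genes 14 of 15 were higher (median log2 change 0.55); 1 rose over all genes, Ddit3, and 9 rose when adjusted over the list alone (camera adjusted p = 1.83e-10, adjusted p = 0.563 with an estimated correlation). Atf4, the transcription factor upstream of many of these genes, which stands in the bone formation list, was at 1.12 (SE 0.26, adjusted p = 0.37). The aryl hydrocarbon and oxidative stress list had 10 of 14 higher (median 0.25, 1 rose, Hmox1, and 3 adjusted over the list alone, adjusted p = 0.0158, adjusted p = 0.629 with an estimated correlation, 0.194 without DMSO replicate 3 and 0.106 without LE540 replicate 3). Immediate early genes had 10 of 12 higher (median 0.18, adjusted p = 0.0158, adjusted p = 0.72 with an estimated correlation, 0.286 without DMSO replicate 3 and 0.19 without LE540 replicate 2), with Jun at 0.73 (SE 0.22) and 0 members passing adjusted over the list alone. LE540 replicate 1, the array that stood apart, is among these arrays, and the stress list had a median of 0.47 without it.

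Cell cycle, TGF-beta and BMP, cholesterol, elastic fibre and proteoglycan lists fell with LE540, with no single member passing over all genes, while collagens (adjusted p = 0.732, median -0.01) and matrix proteases (adjusted p = 0.131) did not pass. Cell cycle genes had 22 of 23 members lower (median -0.50, 1 fell adjusted over the list alone, adjusted p = 3.1e-08, adjusted p = 0.72 with an estimated correlation), with the mitotic kinase Bub1 at -1.71 (SE 0.56, adjusted p = 0.529) and Top2a, a DNA topoisomerase, at -1.25 (SE 0.39). TGF-beta and BMP signalling had 21 of 24 lower (median -0.35, 2 fell adjusted over the list alone, adjusted p = 1.15e-05, adjusted p = 0.563 with an estimated correlation), with Tgfb3, a TGF-beta ligand, at -1.33 (SE 0.20, adjusted p = 0.155). Cholesterol synthesis had 15 of 15 lower (median -0.40, adjusted p = 0.000386, adjusted p = 0.72 with an estimated correlation), with Idi1, an isomerase of the pathway, at -1.62 (SE 0.53). Elastic fibre genes had 10 of 14 lower (median -0.23, 2 fell adjusted over the list alone, adjusted p = 0.0128, adjusted p = 0.563 with an estimated correlation, 0.124 with a median of -0.12 without LE540 replicate 1 and 0.133 with the Y-linked score), with Ltbp1, a TGF-beta binding protein, at -0.96 (SE 0.28). Proteoglycans and hyaluronan genes had 16 of 22 lower (median -0.19, adjusted p = 0.0929, adjusted p = 0.72 with an estimated correlation, 0.369 with a median of -0.12 without DMSO replicate 3 and 0.812 with a median of -0.08 without LE540 replicate 1), with Ogn, a small leucine-rich proteoglycan, at -1.68 (SE 0.73).

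Retinoic acid targets did not pass with LE540. The list had 11 of 17 members higher (median 0.09, mean -0.10, adjusted p = 0.924), and none of its members passed. Dhrs3 was at -0.38 (95% confidence interval -1.16 to 0.39), Rarb at -0.57 (-1.62 to 0.49), Cyp26a1 at 0.03 (-0.33 to 0.38) and Cyp26b1 at 0.22 (-0.10 to 0.54). Meis1 and Meis2, homeobox genes of the list, were at -1.04 (SE 0.34) and -1.03 (SE 0.34) with an adjusted p of 0.529 each. Sox9 was at -0.35 (-0.70 to -0.00361, adjusted p = 0.563) and Mgp at -0.38 (-0.82 to 0.07). Ank was at -0.75 (SE 0.17, adjusted p = 0.369), and its list, the mineralization inhibitors, did not pass (0.393). The 28 lists that did not pass had adjusted p from 0.131 to 0.924, among them cartilage (0.437), bone formation (0.924), contractile genes (0.393), cytokines and inflammation (0.547), cardiomyocyte (0.407), endothelial (0.924) and macrophage markers (0.312). Ccl5, a chemokine of the cytokine list, was at 3.08 (SE 0.94, adjusted p = 0.502). Median, mean and test differed in sign for 8 lists, of which 0 passed.

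The third comparison sets ATRA against LE540 directly and does not use the DMSO arrays for its difference, although they enter the shared estimate of spread. The labels give 1 µmol/L for ATRA and no dose or vehicle for LE540, so the doses cannot be said to match. Here the retinoic acid targets differed widely. Dhrs3 was 9.16-fold higher with ATRA, at 3520 ± 1099 against 371 ± 32.0 (SD, n = 3 arrays each, log2 change 3.19, SE 0.34, adjusted p = 0.0123). Rarb was 7.05-fold higher, at 1125 ± 431 against 165 ± 83.2 (log2 change 2.82, SE 0.46, adjusted p = 0.0595). Tgm2 differed by 2.18 (SE 0.11, adjusted p = 0.000395) and Cyp26a1 by 1.22 (SE 0.16, adjusted p = 0.0236).

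The largest rise among probe sets with a listed gene was that of Olr1 (probe set 10548385), a scavenger receptor for oxidized lipoprotein, 10.4-fold higher with ATRA at 531 ± 207 against 48.7 ± 7.11, itself below the lower quartile (adjusted p = 0.0269, 0.1 without ATRA replicate 1). Piezo2 (probe set 10459335) was 9.42-fold higher (adjusted p = 0.0123), Fap differed by 3.09 (SE 0.21, adjusted p = 0.00138) and Pparg by 2.71 (SE 0.18, adjusted p = 0.00138). On the LE540 side stood Slc7a11 (10498024), the cystine importer, at 141 ± 78.0 with ATRA against 1512 ± 468 (log2 change -3.53, SE 0.58, adjusted p = 0.0608), Mt2 at -3.50 (SE 0.39, adjusted p = 0.015) and Mt1 at -2.13 (SE 0.30, adjusted p = 0.0347). Cxcl10 (10531415), an interferon-induced chemokine, stood at -2.12 (SE 0.36, adjusted p = 0.0614) and Asns (10543067), which makes asparagine, at -2.01 (SE 0.30, adjusted p = 0.0451). Without 1 array at a time Slc7a11 lost its call in 6 cases (adjusted p = 0.101 to 0.21), Cxcl10 in 6 (0.101 to 0.199), and Asns (0.109 and 0.143) and Mt1 (0.116 and 0.131) in 2 each.

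In limma 141 of 23397 probe sets passed, 96 higher and 45 lower with ATRA, for 132 genes with a single symbol per probe set, and 98 of them differed over 2-fold (73 up, 25 down); 2231 had an unadjusted p under 0.05. With the replicate number as a block 221 passed (158 up, 63 down, 122 shared), and with the cardiomyocyte score as a covariate 55. The count was 61 without DMSO replicate 1, 73 without DMSO replicate 2, 54 without DMSO replicate 3, 66 without ATRA replicate 1, 61 without ATRA replicate 3, 67 without LE540 replicate 1, 278 without LE540 replicate 2 and 273 without LE540 replicate 3. Of the 25 genes named by the rule that passed, 11 passed with any 1 array left out, among them Tgm2, Pparg, Fap, Dhrs3, Piezo2, Mt2, Ddit3, Hmox1, Tgfb3 and Smad3, and the others reached an adjusted p of up to 0.298 (Efemp1, without ATRA replicate 1). For Piezo2 this was checked on its brightest probe set (10459353, 3.00 log2), not on the probe set named above. Cxcl12, a chemokine of the cytokine list, did not pass in the main fit (1.90, SE 0.41, adjusted p = 0.151, or 0.0878 with the replicate block).

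The DMSO level placed these genes between the treatments. Of the 96 probe sets higher with ATRA, DMSO lay between ATRA and LE540 for 87, and a median of 66.1% of the distance lay between ATRA and DMSO; 17 also passed in ATRA vs DMSO. Of the 45 lower with ATRA, DMSO lay between for 32, with a median of 15.8% of the distance between ATRA and DMSO; 7 also passed in LE540 vs DMSO. Genes chosen for a large difference between both treatments tend to have DMSO between them by chance alone.

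Among the lists, retinoic acid targets rose with 11 of 17 members higher and 6 lower (6 rose over all genes and 10 adjusted over the list alone, median 0.38, camera adjusted p = 1.66e-09, adjusted p = 0.0374 with an estimated correlation). Besides Dhrs3, Rarb, Tgm2 and Cyp26a1, Meis2 rose (1.81, SE 0.34, adjusted p = 0.0927, or 0.134 with the replicate block and 0.119 with the Y-linked score). Matrix proteases and inhibitors had 21 of 22 members higher (median 0.35, 6 rose adjusted over the list alone, adjusted p = 1.73e-07, adjusted p = 0.0394 with an estimated correlation). Elastic fibre genes had 12 of 14 higher (median 0.54, 1 rose, Efemp1 by 2.42 with an adjusted p of 0.0957, or 0.14 with the Y-linked score, and 7 adjusted over the list alone, adjusted p = 1.37e-06, adjusted p = 0.0737 with an estimated correlation). TGF-beta and BMP signalling had 18 of 24 higher (median 0.36, adjusted p = 7.2e-08, adjusted p = 0.17 with an estimated correlation), and 3 rose: Tgfb3 (2.07, SE 0.20, adjusted p = 0.00791), Bmp2 (1.59, SE 0.24, adjusted p = 0.0456) and Smad3, a signal transducer of TGF-beta (1.26, SE 0.12, adjusted p = 0.00791). Proteoglycans and hyaluronan genes had 15 of 22 higher (median 0.22, adjusted p = 0.00036, adjusted p = 0.229 with an estimated correlation), and Vcan, the large proteoglycan versican, rose by 1.29 (SE 0.22, adjusted p = 0.0608). Adjusted over the list alone, 6 TGF-beta and BMP genes and 5 proteoglycan list genes rose.

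Contractile genes had 15 of 16 higher (median 0.40, 4 rose adjusted over the list alone, adjusted p = 3.71e-06, adjusted p = 0.229 with an estimated correlation), and collagens 12 of 17 (median 0.13, adjusted p = 0.00534, adjusted p = 0.351 with an estimated correlation, 0.109 without LE540 replicate 1). Cholesterol synthesis had 15 of 15 higher (median 0.71, 5 rose adjusted over the list alone, adjusted p = 1.73e-07, adjusted p = 0.351 with an estimated correlation), with Fdft1, which makes squalene, at 1.13 (adjusted p = 0.248, or 0.0495 with the replicate block). Cell cycle genes had 21 of 23 higher with ATRA (median 0.25, adjusted p = 0.000406, adjusted p = 0.526 with an estimated correlation, 0.109 with a median of 0.11 without LE540 replicate 1). Notch signalling (median 0.33, adjusted p = 0.00272, adjusted p = 0.341 with an estimated correlation) and Wnt signalling (median 0.10, adjusted p = 0.00331, adjusted p = 0.229 with an estimated correlation) were higher, and Lgr6 rose by 0.67 (adjusted p = 0.0451). Mineralization inhibitors (median 0.10, adjusted p = 0.0535, adjusted p = 0.341 with an estimated correlation, 0.187 without ATRA replicate 1, 0.112 without ATRA replicate 2 and 0.2 with a median of 0.03 without LE540 replicate 3) and the p53 response (median 0.10, adjusted p = 0.0812, adjusted p = 0.425 with an estimated correlation, 0.164 without ATRA replicate 1, 0.278 without ATRA replicate 3, 0.396 without LE540 replicate 2, 0.241 without LE540 replicate 3 and 0.125 with the Y-linked score) passed narrowly. Twist2 rose by 0.93 (adjusted p = 0.0526) although valve mesenchyme transcription factors did not pass (adjusted p = 0.174). Adjusted over the list alone, 2 collagen list genes and 5 Wnt genes rose, 1 Wnt gene fell, and 0 genes of the cell cycle, Notch, mineralization and p53 lists passed.

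Stress lists were lower with ATRA than with LE540. Unfolded protein and amino acid stress genes had 14 of 15 lower (median -0.52, 10 fell adjusted over the list alone, adjusted p = 9.38e-10, adjusted p = 0.221 with an estimated correlation), and 3 fell: Asns, Ddit3 (-2.01, SE 0.21, adjusted p = 0.0123) and Chac1, which splits glutathione (-1.70, SE 0.27, adjusted p = 0.0537). The aryl hydrocarbon and oxidative stress list had 11 of 14 lower (median -0.26, adjusted p = 0.0037, adjusted p = 0.229 with an estimated correlation), and Slc7a11 and Hmox1 (-1.65, SE 0.20, adjusted p = 0.0171) fell. Immediate early genes had 12 of 12 lower (median -0.38, 6 fell adjusted over the list alone, adjusted p = 0.00036, adjusted p = 0.351 with an estimated correlation), with Ier2 at -0.98 (SE 0.29, adjusted p = 0.307).

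Cell type markers moved here too. Cardiomyocyte markers had 15 of 19 lower with ATRA (median -0.39, adjusted p = 0.013, adjusted p = 0.536 with an estimated correlation, 0.126 without ATRA replicate 1, 0.235 with a median of -0.16 without ATRA replicate 3 and 0.241 without LE540 replicate 3). Endothelial markers had 18 of 20 higher (median 0.17, adjusted p = 0.00107, adjusted p = 0.459 with an estimated correlation, 0.507 with a median of 0.03 without ATRA replicate 2), with 0 passing adjusted over the list alone and Emcn at 1.84 (adjusted p = 0.449, or 0.0144 with the replicate block). Macrophage markers had 13 of 18 higher (median 0.23) and an adjusted p of 0.1002, or 0.0421 with the replicate block and 0.578 with an estimated correlation. The 18 lists that did not pass had adjusted p from 0.1002 to 0.99. Cartilage was among them (0.326), as was bone formation (0.367), with Sox9 at 0.22 (95% confidence interval -0.12 to 0.57). Median, mean and test differed in sign for 5 lists, of which 0 passed.

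**Figure D3:**
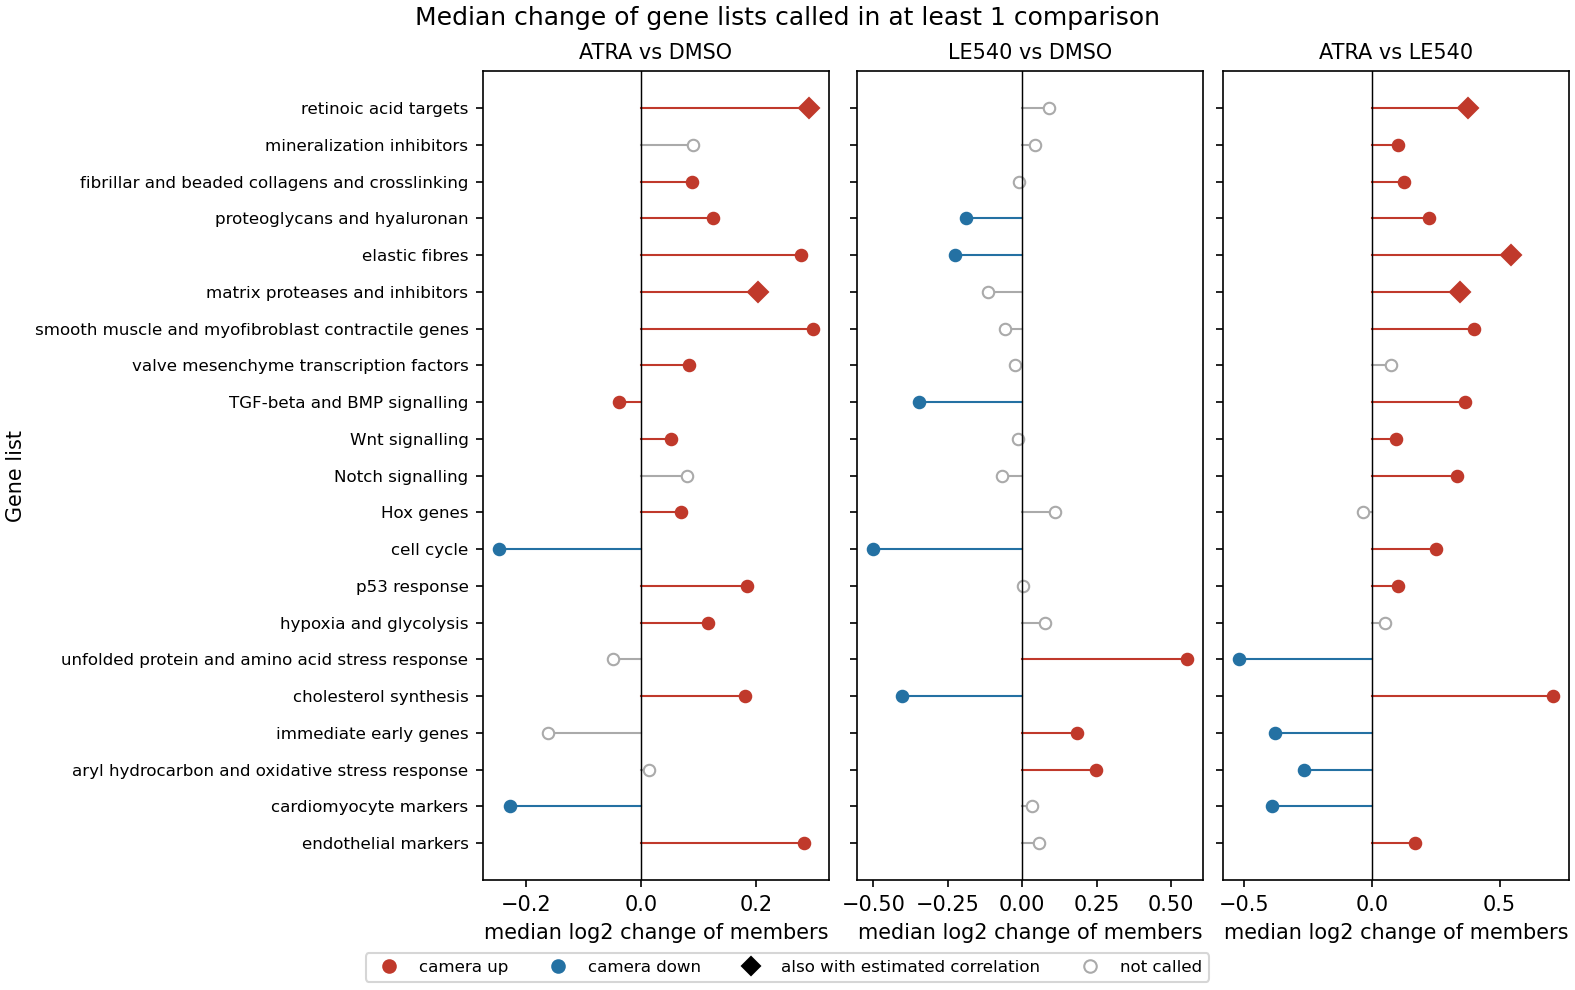
Median log2 change of members (horizontal axis, its scale differing between panels) for the gene lists that passed in at least 1 comparison (vertical axis). Red and blue symbols mark lists that camera called up and down, diamonds those also called with an estimated correlation (2, 0 and 3 lists from left to right), and open grey circles lists not called.

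Across lists, 16 of 36 passed camera in ATRA vs DMSO (14 up, 2 down), 8 in LE540 vs DMSO (3 up, 5 down) and 18 in ATRA vs LE540 (14 up, 4 down). With an estimated correlation 2, 0 and 3 of these held: retinoic acid targets and matrix proteases in ATRA vs DMSO, none in LE540 vs DMSO, and retinoic acid targets, matrix proteases and elastic fibres in ATRA vs LE540. Of these, matrix proteases in ATRA vs DMSO did not pass with fry (adjusted p = 0.187), whereas the others did. Without 1 array at a time, 5 of 16, 4 of 8 and 12 of 18 lists kept their call throughout. With the Y-linked score 8 of 16, 1 of 8 and 1 of 18 lost or turned theirs. In 1 simulated set described with the processing, 6 of 35 lists without a shift were called too. Over 60 sets with no shift, 4.86% of list tests had an unadjusted p under 0.05, but genes were simulated independently. Members of a list can be correlated, up to 0.74 for cholesterol synthesis, so a single list call carries limited weight.

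The changes with ATRA and with LE540 were also set against each other. Log2 changes against the shared DMSO arrays correlated at r = 0.259 across 23397 probe sets, where unchanged groups of equal, independent spread gave 0.498 (0.469 to 0.531) in 100 simulations. The spread was not equal, with a mean variance of 0.0501 in DMSO, 0.0722 in ATRA and 0.111 in LE540 arrays. With the spread of each group 100 simulations gave 0.355 (0.333 to 0.401), and with the correlation of equal replicate numbers as well 0.438 (0.415 to 0.477). All these simulations drew probe sets independently of each other, so their ranges are too narrow for genes that vary together. Without 1 array at a time the observed r ran from 0.166 to 0.392, so its place against the simulated values is uncertain. With the Y-linked score as a covariate the observed r was 0.489, for which no simulation was run, so the value depends on the fit. The covariance was 0.0184, against 0.0207 simulated with equal spread, 0.0133 with the spread of each group and 0.0135 with the replicate numbers as well. In all, 64.0% of probe sets changed in the same direction, against 66.7%, 61.6% and 64.5% simulated. In limma 0 probe sets passed in both comparisons; 1099 had an unadjusted p under 0.05 with ATRA and 2060 with LE540.

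**Figure D4:**
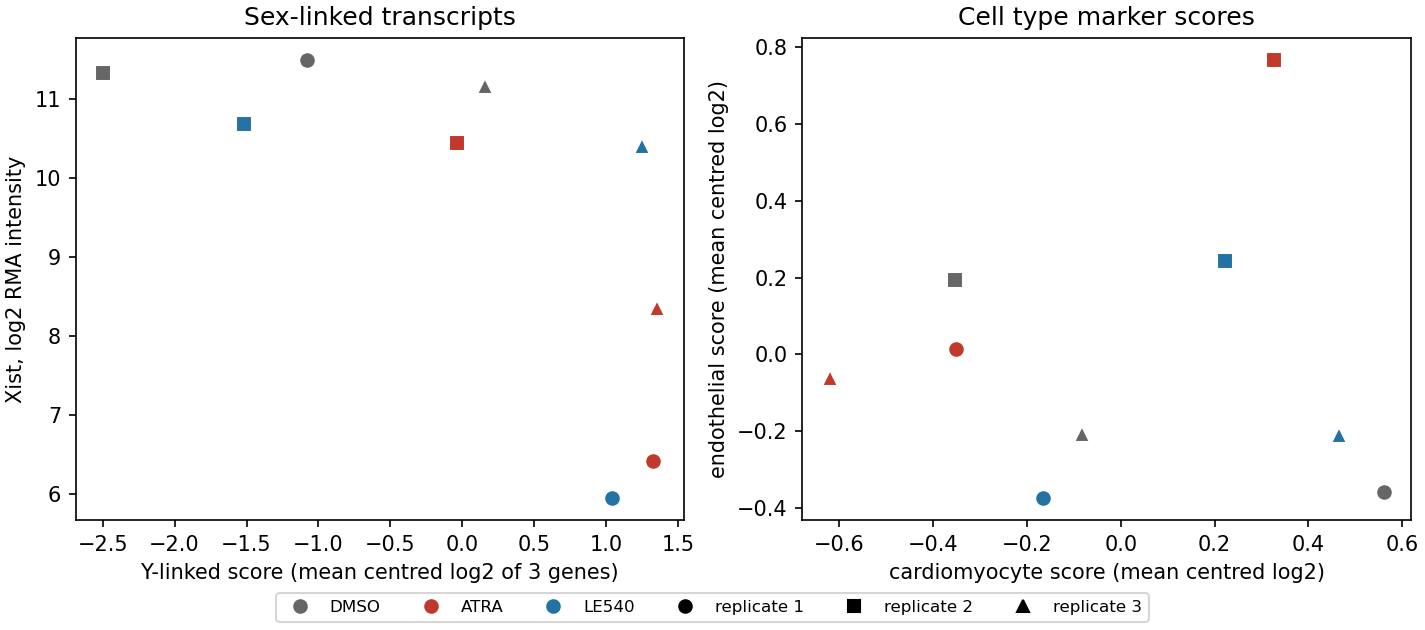
Left, log2 Xist intensity (vertical axis) against the Y-linked score (horizontal axis, mean centred log2 of 3 genes); right, endothelial score (vertical axis) against cardiomyocyte score (horizontal axis, both mean centred log2), with 1 point per array, coloured by group and shaped by replicate number. Xist was lowest in LE540 replicate 1 (61.6) and ATRA replicate 1 (85.7) and 2294 or more in all 3 DMSO arrays.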

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

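Of the tests in this part, those with the Y-linked score as a covariate, on LE540 replicate 1 alone, on tRNA synthetases, on a lower share of myocardium, on changes over arrays, on a mislabelled array, and on Xist and the Y-linked score were chosen after the result was seen.

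Among the 4873 rows with no listed gene, which the main fits left out, 3 passed when all rows were fitted, in ATRA vs DMSO (2 up, 1 down), 0 in LE540 vs DMSO and 8 in ATRA vs LE540 (7 up). In ATRA vs DMSO 2 of them carried a signal above the DMSO controls. Probe set 10377537 was higher with ATRA by 1.1 log2 (adjusted p = 0.0109), at a mean intensity of 4387 against 2054 with DMSO and 1550 with LE540. Probe set 10521678 was higher by 1.74 log2 (adjusted p = 0.0494), at 825 against 239 and 127. The probe set that fell was 10450798, by 1.13 log2 (adjusted p = 0.0494). In ATRA vs LE540 the largest difference was that of probe set 10358339, by 3.48 log2 (adjusted p = 0.0504, 2615 against 284).

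The first pattern is that the unfolded protein and amino acid stress genes were higher with LE540 than with DMSO (median 0.55), a list call that was lost with an estimated correlation (adjusted p = 0.563). LE540 replicate 1, the array that stood apart, does not carry it alone, since the median was 0.471 without that array (camera adjusted p = 1.04e-10, mean over arrays 0.657, SE 0.155). With the Y-linked score as a covariate the median was 0.637 (camera adjusted p = 5.25e-10, mean over arrays 0.813, SE 0.234). This argues against a different share of male pups only so far as the score tracks that share, which the third pattern below leaves open. The score was also lowest in replicate 2 of every group. An amino acid stress programme stays open as a source of the higher stress genes. The tRNA synthetases cannot single it out, as no genes that part it from an unfolded protein response were tested. In the same arrays 18 cytosolic tRNA synthetases, none of them in the stress list, had a median of 0.593 with 16 higher. For these camera gave p = 1e-12, or 0.0485 with an estimated correlation, and for 16 mitochondrial synthetases (median -0.00953) camera gave p = 0.804. Cars, Nars and Sars passed in ATRA vs LE540 and were known to differ, and without them the median was 0.451 (p = 1.88e-08, and 0.0747 with an estimated correlation), with a mean over arrays 0.515 (SE 0.155) above that of the mitochondrial synthetases. Whether LE540 itself or an unstated vehicle or dose raised these genes stays open, as the labels do not give them.

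The second pattern is that matrix protease, contractile and endothelial lists passed upward in ATRA vs DMSO, the last 2 not with an estimated correlation (adjusted p = 0.387 and 0.581), and over arrays the mean of their members changed by 0.329 (SE 0.134), 0.389 (SE 0.232) and 0.364 (SE 0.296), with a 95% confidence interval above 0 for the first list alone. The changes over arrays in this paragraph were fitted without the replicate number, so their errors ignore the pairing of ATRA and DMSO arrays. By replicate number, the endothelial score was 0.01 with ATRA against -0.36 with DMSO, 0.77 against 0.19, and -0.06 against -0.21. A different share of male pups stays open for the 3 lists. With the Y-linked score as a covariate 3 of the 3 lists passed camera upward. Over arrays matrix proteases and contractile genes then changed by 0.239 (SE 0.177) and 0.396 (SE 0.326), and endothelial markers by 0.833 (SE 0.246). In every group, however, replicate 2 had the lowest Y-linked score and the highest endothelial score. That covariate therefore cannot separate sex from replicate number for endothelial markers. Less myocardium in the ATRA pools stays open too, since endothelial minus macrophage markers changed by 0.36 (SE 0.328) over arrays. With the cardiomyocyte score as a covariate 3 of the 3 lists passed camera upward. Over arrays they then changed by 0.358 (SE 0.147), 0.338 (SE 0.253) and 0.428 (SE 0.323), each interval including 0. A larger endothelial share in some ATRA pools could also underlie the endothelial call, which was lost without ATRA replicate 2 (adjusted p = 0.421). The dissection of the valves and other differences between the pools of pups were not tested.

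The third pattern is that Y-linked transcripts were higher and Xist lower on average in ATRA and LE540 arrays than in DMSO arrays, by 1.71 (SE 0.85) in the Y-linked score and -2.62 (SE 1.28) in log2 Xist, each 95% confidence interval including 0. On a single mislabelled array these signals cannot decide, as the labels give no pup sex. The differences were 1.03 (SE 0.904) without DMSO replicate 2 and -2.07 (SE 1.1) without LE540 replicate 1. Retinoid genes fixed before the data were examined argue against an exchange between ATRA and other arrays. The lowest ATRA array lay at 11.1 log2 for Dhrs3 and 9.38 for Rarb, and the highest other array at 9.31 and 8.49. Stra6, also fixed, hardly changed. An exchange of DMSO and LE540 arrays stays open, since genes such as Mt2 were chosen by those labels. Single pools did differ in both signals. Xist was 61.6 in LE540 replicate 1 and 85.7 in ATRA replicate 1, where the Y-linked Eif2s3y was 579 and 664. In DMSO replicate 2 Xist was 2589 and Eif2s3y 22.55, while LE540 replicate 3 had both high, at 1361 and 701. Whether the share of male pups differed by group stays open, since a relation over all 9 arrays follows from the pattern itself. The test within groups, with 3 arrays in each, cannot decide it. Within groups, deviations of the Y-linked score and of log2 Xist had Pearson r = -0.479 (exact permutation p = 0.333 over 216 orders) and Spearman rho = -0.533 (exact permutation p = 0.204), with r = -0.421 and rho = -0.393 without the 2 arrays farthest from the median. No treatment effect on these genes was tested apart from the groups.

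For each comparison the 6 arrays can be split in 10 ways, which is too few for a share under 0.05. In ATRA vs DMSO 1 split, the real one, called as many as 19 probe sets, and the highest of the others called 0. In LE540 vs DMSO 1 split called as many as 7, and the highest of the others called 1. In ATRA vs LE540 1 split called as many as 141, and the highest of the others called 0. In both paired comparisons, the other 3 of the 4 splits that part all pairs called 0 as well.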

How the results depend on the processing

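The fits with the Y-linked score, with the cardiomyocyte score and with 1 probe set per gene were chosen after seeing the data, and the other alternatives before. Calls in ATRA vs DMSO (main count 19, and 14 over 2-fold) numbered 9 (8 over 2-fold) with only the 6 arrays of both groups, 29 (26) with the replicate block, 9 (7) with the dimmer 50% of probe sets left out, 71 (43) with array weights, 7 (7) with the Y-linked score, 8 (7) with the cardiomyocyte score, 12 at 1 probe set per gene, 8 at an adjusted p under 0.05 and 3 under 0.01. In LE540 vs DMSO (7, and 7) they numbered 1 (1) with the 6 arrays, 1 (1) with the block, 0 (0) after quantile normalization, 0 (0) with all rows tested, 0 (0) with the cardiomyocyte score, 12 (11) at 1 probe set per gene, and 0 at 0.05 and 0 at 0.01, beside 2060 with an unadjusted p under 0.05. In ATRA vs LE540 (141, and 98) they numbered 25 (24) with the 6 arrays, 221 with the block, 55 (49) with the cardiomyocyte score, 60 at 0.05 and 9 at 0.01. Stricter thresholds lower counts by construction, and the cause of the other shifts was not tested. Without 1 array at a time, counts ran from 4 to 22 (over 2-fold 4 to 20) in ATRA vs DMSO, 0 to 297 (0 to 121) in LE540 vs DMSO and 54 to 278 (50 to 183) in ATRA vs LE540. Lists called ran from 9 to 18, 5 to 12 and 16 to 19. With an estimated correlation 2, 0 and 3 lists were called, and with fry 1, 0 and 10. The correlation of both fold changes was 0.489 with the Y-linked score, 0.161 with the cardiomyocyte score, and 0.166 to 0.392 without 1 array.

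Among lists called in the main fit or under the alternative, the direction of the test turned in 6 cases; turns of lists called in neither, as some had with fry, are not counted. Cell cycle genes in ATRA vs DMSO had a median of 0.186 (adjusted p = 0.000839) and endothelial markers in LE540 vs DMSO 0.331 with the test turned upward (adjusted p = 0.0286) with the Y-linked score, and the cause was not tested. Cholesterol synthesis in ATRA vs DMSO was at -0.117 (adjusted p = 0.604) without ATRA replicate 3, in a range of -0.117 to 0.593 without 1 array, and cardiomyocyte markers at -0.00154 with the test turned upward (adjusted p = 0.787) without DMSO replicate 1, in a range of -0.423 to -0.00154. The cause was not tested. Cardiomyocyte markers with the cardiomyocyte score, which is built from them, were at 0.0152 (adjusted p = 0.844) in ATRA vs DMSO and 0.0731 (adjusted p = 0.635) in ATRA vs LE540. Besides these, medians of 5 lists called in ATRA vs DMSO changed sign in 11 cases while the test kept its direction, with the call lost in 7 and kept in 4: TGF-beta and BMP signalling (-0.0383, up to 0.0824), proteoglycans (-0.00298 without DMSO replicate 2 and -0.0191 with the Y-linked score) and, with that score, valve mesenchyme transcription factors (-0.00767), Hox genes (-0.00934) and the p53 response (-0.143). The cause was not tested. Of 42 list calls, 41 held with the 6 arrays, 40 with the block, 38 after quantile normalization, 42 with arrays centred on their median, 38 with either dim filter, 42 with an intensity trend or a robust prior, 41 with array weights, 32 with the Y-linked score and 37 with the cardiomyocyte score. Of 44 calls of named genes, 35 held with the block, 35 after quantile normalization, 44 with centred arrays, 41 with array weights, 28 with the Y-linked score, 18 with the cardiomyocyte score and 21 with the 6 arrays, and none changed sign. In LE540 vs DMSO the block gave adjusted p of 0.114 to 0.164 for the 7 genes that passed, except 0.0383 for Mt1, and among lists and named genes it changed no other call beyond those printed with each comparison. Signal over background is unknown from these values, so dim probe sets carry less certainty.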

Other observations

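Of the values in this part, the genes of serine, amino acid and lipid metabolism and the growth factors were chosen after the result was seen, and the test on Slc30a1 before.

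Several metabolic genes, of which Mthfd2 alone is named by the rule, were lower with ATRA than with LE540. Psat1 and Phgdh, enzymes of serine synthesis, stood at -1.48 (SE 0.16, adjusted p = 0.0139) and -1.15 (SE 0.18, adjusted p = 0.0472). Shmt2 and Mthfd2, enzymes of mitochondrial one-carbon metabolism, stood at -1.44 (SE 0.22, adjusted p = 0.0472) and -1.77 (SE 0.22, adjusted p = 0.0185). Mthfd2 averaged 473 with DMSO, 479 with ATRA and 1609 with LE540. Of all 45 probe sets lower with ATRA than with LE540, DMSO lay closer to ATRA for 39 and to LE540 for 6. Slc3a2, the partner chain of Slc7a11, averaged 727 with ATRA against 2473 with LE540 (adjusted p = 0.0619), and 3 tRNA synthetase genes were lower with ATRA: Sars at -1.20, Cars at -0.88 and Nars at -0.60.

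Other genes outside the naming rule differed either way between ATRA and LE540. Hgf, hepatocyte growth factor, averaged 429 with ATRA against 93.6 with LE540 (2.21, SE 0.36, adjusted p = 0.0589), Igf1 1197 against 330 (1.90, SE 0.26, adjusted p = 0.0357) and Fgf2 815 against 324 (1.33, SE 0.19, adjusted p = 0.0402). This contrast alone does not tell which treatment moved Hgf, Igf1 and Fgf2. Scd1 and Scd2, stearoyl-CoA desaturases, differed by 2.77 (SE 0.44, adjusted p = 0.0539) and 1.98 (SE 0.31, adjusted p = 0.0502). Their DMSO means were 403 and 411, nearer to the ATRA means of 733 and 538 than to the LE540 means of 93.0 and 132 on the log2 scale. Among lipid genes Star, which carries cholesterol into mitochondria, and Acot2, an acyl-CoA thioesterase, went the other way, at -1.29 (SE 0.17, adjusted p = 0.0258) and -0.77 (SE 0.13, adjusted p = 0.0619). Foxc2, a forkhead factor of valve development, was higher by 0.83 (SE 0.16, adjusted p = 0.0934).

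A hypothesis is that Mt1 and Mt2 rose with LE540 as part of a metal response, which may also raise the zinc exporter Slc30a1. Slc30a1 was at 0.769 log2 with LE540 (95% confidence interval 0.468 to 1.07), above 0, although it did not pass over all genes (adjusted p = 0.206). In ATRA vs LE540 it stood at -0.92 log2 (adjusted p = 0.0401). Metal was not measured, and the finding comes from the same arrays as the pattern.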
